A study of Homo sapiens with 12 samples.

How the data were processed

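The series measured how often each guide RNA of a genome-wide CRISPR-Cas9 library was found in sorted cells. Per the labels, HEK293WT cells, a human embryonic kidney line, carried Cas9 and SP1-MHI, a fluorescent reporter used as an indicator of mild hypothermia. Cells with stable guides were selected with puromycin for about 6 days and kept at 32 °C for the last 16 h. The labels do not agree on the hours of selection. The 5% of cells with the strongest fluorescence (high) and the 5% with the weakest (low) were collected by flow sorting. The control was the same line with Cas9 and guides but without the reporter, and it was not described as sorted by fluorescence. Each of the 3 groups had 4 biological replicates, which made 12 libraries. Guides were amplified from genomic DNA and sequenced as single reads. There was no library of the starting guide pool among the samples.

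Per the submitters' processing notes, the authors processed the reads with MAGeCK; its version, the read filters, the guide matching settings and the normalisation option are not given in the sources used here. The labels name a merged read file for replicate 1 of each group. The authors deposited 2 tables of normalised guide counts, 1 with the high and control libraries and 1 with the low and control libraries, whose values were treated as a signal. Each value proved to be a read count multiplied by a size factor of its library, since 100% of the values of every library were whole multiples of the library's smallest value within a tolerance of 0.01. The sums of these whole reads equalled the matched reads that the authors' deposited count summaries list. The same control libraries had different size factors in the 2 tables. Comparisons with control therefore stayed within a table, and high against low used values relative to the controls of each table. The count summaries also give, per the file headers, the read counts of each library, the percent of reads matched to a guide and the Gini index, a fraction that is 0 when every guide has the same number of reads. The authors' deposited gene tables give a robust rank aggregation score, a p-value and a false discovery rate (FDR) for each direction, and a log2 fold change per gene. Their guide tables list each guide 4 times, which shows that the authors' test ran in paired mode. This was learned after the design below was fixed. The 8 columns of the guide tables that hold values per pair of libraries were not used.

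The library listed 119461 guides, with 63950 in part A and 55511 in part B. They included 1000 non-targeting guides and 6834 guides against 1795 microRNA genes. Of 18913 other gene names, 18154 had 6 guides. A total of 17372 of these names were current symbols in the RefSeq annotation of GRCh38.p14, 1352 were older names of 1 gene, 64 were older names of several genes and 125 had no match. Names are given as the files give them. A spreadsheet had turned 1 name, with 9 guides, into a date.

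Before the data were examined, the design, the gene lists, the alternatives and the rule for naming genes were fixed. Guides with a mean deposited value of at least 20 over the libraries of a table were kept, and log2 of the value plus 10 was averaged over the kept guides of each gene within a library. Genes with at least 3 kept guides were tested with limma (version 3.58.1, trend and robust options) in R 4.3.3, for 4 libraries against 4 without further terms. P-values were adjusted by Benjamini and Hochberg over all genes of a comparison, and a gene was called at an adjusted p under 0.05. A change is the log2 difference of group means, with its standard error (SE) from limma. For high against low, each guide's log2 value was first taken relative to the mean of the 4 controls of its own table, so these values include the error of shared controls in both arms. Single guides were tested in the same way. For 32 gene lists, camera of limma compared the members with all other genes, with a preset correlation of 0.01 and, as an alternative, an estimated correlation. Random groups of 5 non-targeting guides were put through the gene test. Library measures were compared by two-sided exact permutation tests, whose smallest possible p for 4 against 4 libraries is 0.0286.

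Named genes were chosen by rule. SMYD5, SP1, CIRBP and RBM3 were named in each comparison. Further genes were up to 8 with the largest rise and 8 with the largest fall among called genes with at least 60% of guides in that direction and the same sign in all 4 pairs of libraries of like number. MicroRNA genes and non-targeting groups were left out of this part of the rule. Where fewer than 5 qualified in a direction, those with the smallest p were added up to 5. The first 5 genes in each direction of the authors' deposited tables and up to 4 members with the smallest p of each list described complete the rule. Not every gene that met the rule is described.

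Libraries of like replicate number carry the same day in the labels, so the numbers pair the libraries. Replicates 1 and 2 share a month, and replicates 3 and 4 share another. The mean correlation, across genes, of deviations from the group means was 0.117 for 12 pairs of like number, from −0.11 to 0.54, and −0.04 for 36 pairs of unlike number. High and low of like number had 0.54, 0.17, 0.26 and 0.18 in replicates 1 to 4. Pairs of a control and a sorted library of like number lay between −0.11 and 0.23. A fit with the replicate number as a block was an alternative.

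Other alternatives were pseudocounts of 1 and 50, no filter on guides or a filter at 100, the median or the sum over guides, and rescaling to the same total or to the non-targeting guides. Single replicates and months were left out, and limma was run without its trend and robust options or with library weights. The recovered whole reads were tested with edgeR 4.0.16 (quasi-likelihood test on sums of reads per gene), and guides were tested by robust rank aggregation with 100000 permutations. A setting without 5 libraries was added after the data had been seen. The pipeline was tested on simulated data in which 200 genes were shifted in shuffled libraries. Deviations from the group means were shuffled among guides of like level, each library apart. This removed the shift of all genes between groups and the correlation between genes. The false calls below therefore do not give the rate in the real data. In low against control, limma recovered 96% of rises of 4 on the log2 scale, 32% of rises of 2, 100% of falls of 4 and 50% of falls of 2, with 5 false calls. In high against control it recovered 86%, 6%, 100% and 54% of the same shifts, with 2 false calls. edgeR recovered 0% and 4% of the rises of 4 in low and in high. Rank aggregation recovered 96% and 98% of them, and limma on medians over guides 40% and 20% (0% and 0% of the rises of 2).

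For shares of reads in a library, 95% Wilson intervals were at most 0.0341 percentage points wide. A guide without reads allows up to 3 reads, which is 0.0107 CPM (the usual unit of reads scaled to library size) in control 1, the deepest library, and 0.0909 in control 4, the shallowest. Such intervals and limits cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Tables were handled with python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and data.table in version 1.17.8, and figures were drawn with matplotlib 3.10.9.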

Results

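The screen counted guide RNAs in 12 libraries of HEK293WT cells with Cas9: 4 from reporter cells with the strongest fluorescence after 16 h at 32 °C (high), 4 from reporter cells with the weakest fluorescence (low) and 4 from cells without the reporter (control). Reads matched to a guide numbered 281065678, 128957235, 72508670 and 32991949 in control 1 to 4. High 1 to 4 held 204955865, 67902556, 109841372 and 83190720 matched reads, and low 1 to 4 held 258895850, 41660181, 102058779 and 113561378. Matched reads made up between 16.77% (low 2) and 57.4% (high 4) of all reads. The median guide had 1778, 217, 214 and 63 reads in the controls, 68, 24, 28 and 21 in high, and 130, 18, 17 and 18 in low.

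Guides against genes that every cell needs were scarcer than non-targeting guides in each of the 12 libraries. These were 978 guides against 164 genes of the ribosome, proteasome, core spliceosome and RNA polymerase II. The difference in median log2 value was −1.10 ± 0.33 in control, −1.32 ± 0.36 in high and −1.21 ± 0.13 in low (SD, n = 4 each). Unpaired exact permutation tests gave p = 0.429 for high against control, 0.4 for low against control and 0.771 for high against low. Within pairs of like number the difference was lower in high than in control in 4 of 4 pairs, by a mean of −0.23 ± 0.11 (exact sign p = 0.125, the smallest that 4 pairs can give), and lower in low in 3 of 4 pairs, by −0.13 ± 0.31 (exact p = 0.375). With the mean over guides high was lower in 3 of 4 pairs, by −0.11, and with ribosomal protein genes alone in 3 of 4, by −0.13. The test within pairs was added after the data had been seen. Without a library of the starting pool, unequal representation in that pool enters these differences.

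A small part of the guides held most reads of the sorted libraries. The 5973 most abundant guides of a library, 5% of the total, held 46.6% ± 21.6 of reads in control, 77.8% ± 17.6 in high and 78.7% ± 12.5 in low (SD, n = 4 each). High exceeded control in 4 of 4 pairs by a mean of 31.2 percentage points (exact permutation p = 0.0571, adjusted p = 0.514 over 12 tests; 17.6 points without replicate 1 and at most 40.5 without any other replicate). Low exceeded control in 3 of 4 pairs by 32.1 points (exact p = 0.0857, adjusted p = 0.514; 25.4 to 45.5 points without 1 replicate). Within replicates 1 and 2 the differences were 39.5 points for high and 21.9 for low, and within replicates 3 and 4 they were 22.9 and 42.2. The Gini index was 0.292 ± 0.076 in control, 0.337 ± 0.0469 in high and 0.341 ± 0.064 in low (exact p = 0.429 for both sorted groups). In high 1 the deposited index was 0.28 while 5% of guides held 91.8% of reads. It was therefore not computed on plain read counts and cannot be set beside these shares of reads. Guides without reads numbered 10866 ± 3856 in control, 11096 ± 1025 in high and 10881 ± 3440 in low (exact p = 0.943 and 1).

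**Figure D1:**
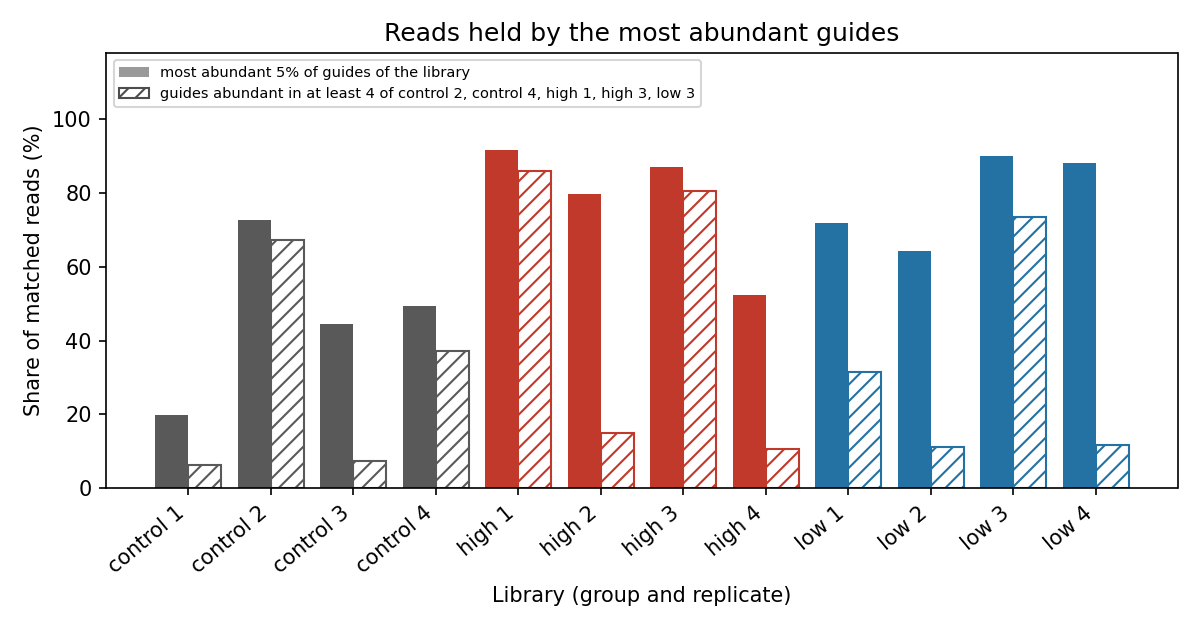
Share of matched reads (%) held, in each library, by its own most abundant 5% of guides (filled bars) and by the 3819 guides that were among the most abundant of at least 4 of control 2, control 4, high 1, high 3 and low 3 (hatched bars). The filled bars run from 19.9% in control 1 to 91.8% in high 1, and the hatched bars from 6.21% in control 1 to 86.1% in high 1.

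The most abundant guides were largely shared by 5 libraries that belong to different groups. Control 2 and high 1 had 5066 of 5973 most abundant guides in common, against 299 by chance. A total of 3819 guides, 54 of them non-targeting, were among the most abundant of at least 4 of control 2, control 4, high 1, high 3 and low 3. They carried 3532 names of genes or non-targeting guides. They held 67.2%, 37.2%, 86.1%, 80.6% and 73.6% of the reads of these libraries, 31.5% in low 1 and between 6.21% and 15.1% in the other libraries. High 2 and high 4 stood apart in another measure, with 76.9% and 69.6% of reads in guides of library part A, against 47.6% to 58.6% in the other 10 libraries.

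**Figure D2:**
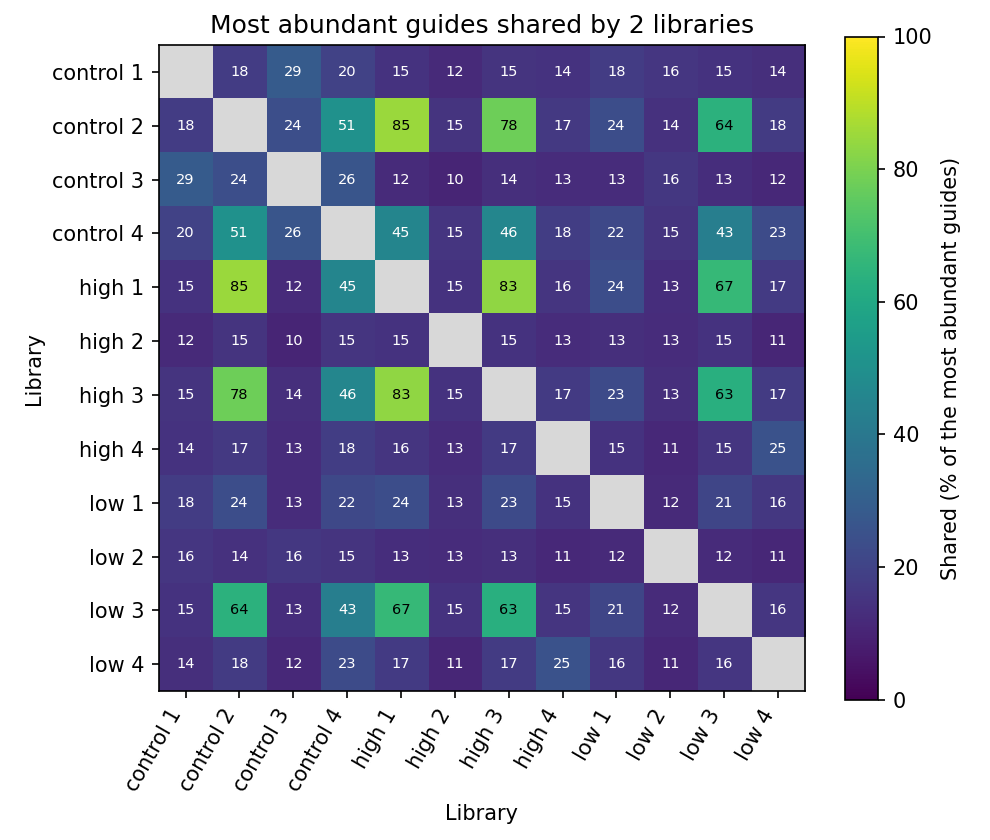
Percent of the 5973 most abundant guides that each pair of the 12 libraries shared (color scale and printed numbers, the diagonal left blank). Pairs among control 2, control 4, high 1, high 3 and low 3 shared between 42.9% and 84.8%.

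High against control compares guides in the cells with the strongest reporter signal with those in cells without the reporter. Line and sorting differ between these groups along with the signal. No gene passed the test here, so the genes that follow are those with the smallest p or fixed beforehand. SMYD5, a lysine methyltransferase of the SET and MYND domain family that the series title calls a regulator of this response, had a change of 2.29 (SE 0.71, n = 4 per group, adjusted p = 0.62). Its guides were higher in 6 of 6 cases and in 4 of 4 pairs, from a mean log2 value of 5.83 ± 0.47 in control to 8.12 ± 2.03 in high. KRT86, a hair keratin, differed by 2.83 (SE 0.66), DDA1, a partner of the DDB1 ubiquitin ligases, by 2.69 (SE 0.69), and CEP250, a centrosomal linker protein, by 2.78 (SE 0.72). Of the genes with lower values, PPIP5K2, an inositol pyrophosphate kinase, differed by −2.08 (SE 0.54), IARS, the cytosolic isoleucyl-tRNA synthetase, by −2.0 (SE 0.54), and NFATC4, a transcription factor of calcineurin signalling, by −2.30 (SE 0.65).

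DTX2, a ubiquitin ligase of the Notch pathway, and BOLA1, a mitochondrial protein, had changes of 2.46 and 2.13, B4GALT2, a galactosyltransferase, of −2.03 and RBKS, ribokinase, of −1.81. Each of these 4 had an adjusted p of 0.62. Over 24 other settings KRT86 and DTX2 passed in 3, SMYD5 and CEP250 in 2, and each other gene named so far for this comparison in 1. SP1, whose name the reporter carries, changed by 0.11 (SE 0.62; −0.33 to 0.42 without 1 library). CIRBP and RBM3, RNA-binding proteins induced by cold, changed by −0.04 (SE 0.56; −0.45 to 0.17 without 1 library) and 0.33 (SE 0.65; −0.29 to 0.64); SP1 and CIRBP lay on the same side of the median of all genes under each scaling tried, and RBM3 did not. In nonsense-mediated decay, 0 of 15 members passed, by either adjustment; RBM8A of the exon junction complex had a change of 1.97 and the kinase SMG1 of 1.65. Among the m6A writers, readers and erasers, 0 of 15 passed and 11 of 15 had lower values, with WTAP of the writer complex at 1.43 and the reader YTHDF3 at −1.06. Of 5 SMYD family members 1, SMYD5, passed when adjusted over the list alone; among the others SMYD1 had a change of −0.88, SMYD2 of 0.73 and SMYD4 of −0.37.

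With limma, 0 of 20157 genes were called, while 1511 had an unadjusted p under 0.05, 1176 of them higher and 335 lower. edgeR called 0 genes and rank aggregation of guides called 0. Of 105962 guides, 0 were called and 9251 had an unadjusted p under 0.05. No list of 32 was shifted relative to the other genes, with a preset or an estimated correlation; the smallest adjusted p of camera was 0.507, for lists such as nonsense-mediated decay and the m6A genes. Rescaled to the same total, 12451 genes were called and all were lower, and rescaled to the non-targeting guides 1822 were called and all were higher, as the median change of all genes went from 0.18 to −1.72 and 0.75. Without high 1, limma called 45 genes, all higher, SMYD5 among them with a change of 3.62 (adjusted p = 0.00447), but SMYD5 changed by 1.48 without high 4, by 0.48 at the same total and by 2.79 on the non-targeting guides, where it passed; without the 5 libraries that shared their most abundant guides, chosen after the data had been seen, it called 186, of which 183 were higher.

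The authors' deposited table for this comparison, from a paired test, holds 1 gene enriched and 1 depleted at an FDR under 0.05. The depleted gene was IARS (FDR 0.0248). Past that FDR the authors' deposited table lists HOXB4, LRRC26, MUC15 and GATAD2A among enriched genes (FDR 0.0718 for HOXB4 and 0.0817 for the rest) and TMEM88B, B4GALT2, OR10R2 and EPM2AIP1 among depleted genes (FDR from 0.190 to 0.277). SMYD5 ranked 53 among enriched genes of the authors' deposited table (FDR 0.174). In the limma fit these genes had changes of 1.59 (HOXB4), 1.94 (LRRC26), 1.49 (MUC15), 1.75 (GATAD2A), −1.79 (TMEM88B), −1.43 (OR10R2) and −1.63 (EPM2AIP1), and none passed. Leaving out 1 library moved several of them: HOXB4 changed by 1.03 without high 1, LRRC26 by 1.15 without high 4, MUC15 by 0.74 without control 1 and GATAD2A by 2.72 without high 1, where it passed. The authors' deposited fold changes and those computed here had a Spearman correlation of 0.783 across genes, which are not independent replicates.

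Low against control compares guides in cells whose reporter stayed weak at 32 °C with those in the same controls. Line and sorting differ here too. Guides of 721 genes rose in low and guides of 0 genes fell. RNASE2, a secreted ribonuclease of eosinophils, rose by 3.92 (SE 0.61, n = 4 per group, adjusted p = 0.00025), and RABGAP1, an activator of Rab GTPases, by 3.5 (SE 0.58, adjusted p = 0.00062). CEP250 rose by 3.11 (SE 0.61, adjusted p = 0.00359) and the microRNA gene hsa-mir-3944 by 4.50 (SE 0.58, adjusted p = 4.02e-06). SMYD5 rose by 2.00 (SE 0.53, adjusted p = 0.0252; 0.0142 with the replicate block, and from 0.0024 to 0.977 over 24 settings), with 5 of 5 guides and 4 of 4 pairs higher, from a mean log2 value of 5.86 ± 0.42 in control to 7.86 ± 1.08 in low. It did not pass at a pseudocount of 50 (1.37), with the median (1.72) or the sum over guides (2.73), with edgeR (3.17), with rank aggregation (1.88), in replicates 1 and 2 (1.21) or 3 and 4 alone (2.54) or without the 5 libraries (1.19), and it changed by −0.58 at the same total. The median of all genes fell at that total too, and SMYD5 lay 1.23 above it.

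Other large rises, microRNA genes left aside by the naming rule, were these. GPR157, an orphan G protein-coupled receptor, rose by 3.57, PNMA6A, of the paraneoplastic antigen family, by 3.5, and RGS21, a regulator of G protein signalling, by 3.45. TMEM108, a transmembrane protein, rose by 3.30, ACTG2, the smooth muscle gamma actin, by 3.29, and KRTAP9-2, a hair protein, by 3.18. All guides kept for these genes were higher, and so were 4 of 4 pairs. The naming rule required all 4 pairs and most guides to be higher. This agreement therefore followed at least in part from the choice of genes and is no separate support for the rises. The genes with the lowest p among lower values did not pass: PPIP5K2 had a change of −1.59 (SE 0.51, adjusted p = 0.0613), IARS of −1.52 (SE 0.51, adjusted p = 0.0726), NFATC4 of −1.63, UBXN8, a protein of the endoplasmic reticulum, of −1.42, and PPCDC, an enzyme of coenzyme A synthesis, of −1.42. All 5 passed at the same total (−4.19 to −3.72), PPIP5K2 (−3.29), UBXN8 (−3.41) and PPCDC (−3.26) with edgeR, PPIP5K2 with library weights (−1.60), PPCDC at a filter of 100 (−1.86) and IARS with no filter on guides (adjusted p = 0.049). PPCDC changed by −0.94 without low 1, −0.93 without control 2 and −0.89 without control 3. SP1 changed by −0.28 (SE 0.51; −0.58 to −0.10 without 1 library), CIRBP by 0.38 (SE 0.51; 0.11 to 0.49) and RBM3 by 0.93 (SE 0.56, adjusted p = 0.355), and none passed.

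Among the SP and KLF transcription factors, which bind GC-rich promoter elements, 2 of 26 members rose, KLF6 by 3.16 (SE 0.55, adjusted p = 0.0013) and KLF4 by 1.91 (adjusted p = 0.0478), and 24 did not pass; 2 passed when adjusted over the list alone. Of the SMYD family, 1 of 5 members rose, SMYD5, and SMYD2 had a change of 1.23 (adjusted p = 0.182). Of 33 members of the Mediator complex, a coactivator of RNA polymerase II, 2 rose, MED22 by 2.58 and MED16 by 2.18, and 3 passed adjusted over the list alone. In the SWI/SNF remodelling complex 2 of 24 rose, BRD9 by 2.28 and ARID1A by 1.99, and 5 passed adjusted over the list alone. The HUSH silencing complex had 0 of 6 members past the threshold over all genes and 3 adjusted over the list alone, with MPHOSPH8 at 1.81 and FAM208A at 1.65. SMG1 rose by 2.34, as 1 of 15 members of nonsense-mediated decay (2 adjusted over the list alone), WTAP by 2.40, as 1 of 15 m6A genes, and LEO1 of the PAF complex by 2.14, as 1 of 30 genes of transcription elongation and Integrator.

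Of 76 mitochondrial ribosomal proteins, 4 rose, such as MRPL34 by 2.17, and of 43 genes of respiratory complex I, 3 rose, such as the assembly factor NDUFAF7 by 3.16. The proteasome had 2 of 39 subunits risen, PSMA5 by 2.33 and PSMA2 by 2.06, and the cytosolic ribosome 0 of 81. None of 11 cold response and thermosensing genes and none of 15 heat shock genes passed, with the cold sensor TRPM8 at 0.93 and the chaperone HSPH1 at 1.55. Lists taken as negative controls had rises as well: 13 of 366 olfactory receptors, such as OR5D16 by 2.72, and 3 of 88 keratin-associated proteins, such as KRTAP5-3 by 2.28. No list of 32 was shifted relative to all other genes with a preset or an estimated correlation; the smallest adjusted p of camera was 0.456, for lists such as nonsense-mediated decay. MicroRNA genes were called more often than other genes, with 146 of 1515 (9.64%) against 575 of 18608 (3.09%; odds ratio 3.34, Fisher's exact p = 3.83e-29). MicroRNA genes have fewer guides, and in a comparison chosen after this result the shares were 11.6% against 7.01% at 3 kept guides (Fisher's exact p = 0.00836) and 8.38% against 4.27% at 4 (Fisher's exact p = 5.47e-06). These tests count genes, which were measured in the same libraries and are not independent replicates. Their p-values therefore do not show whether the difference would recur in other libraries.

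**Figure D3:**
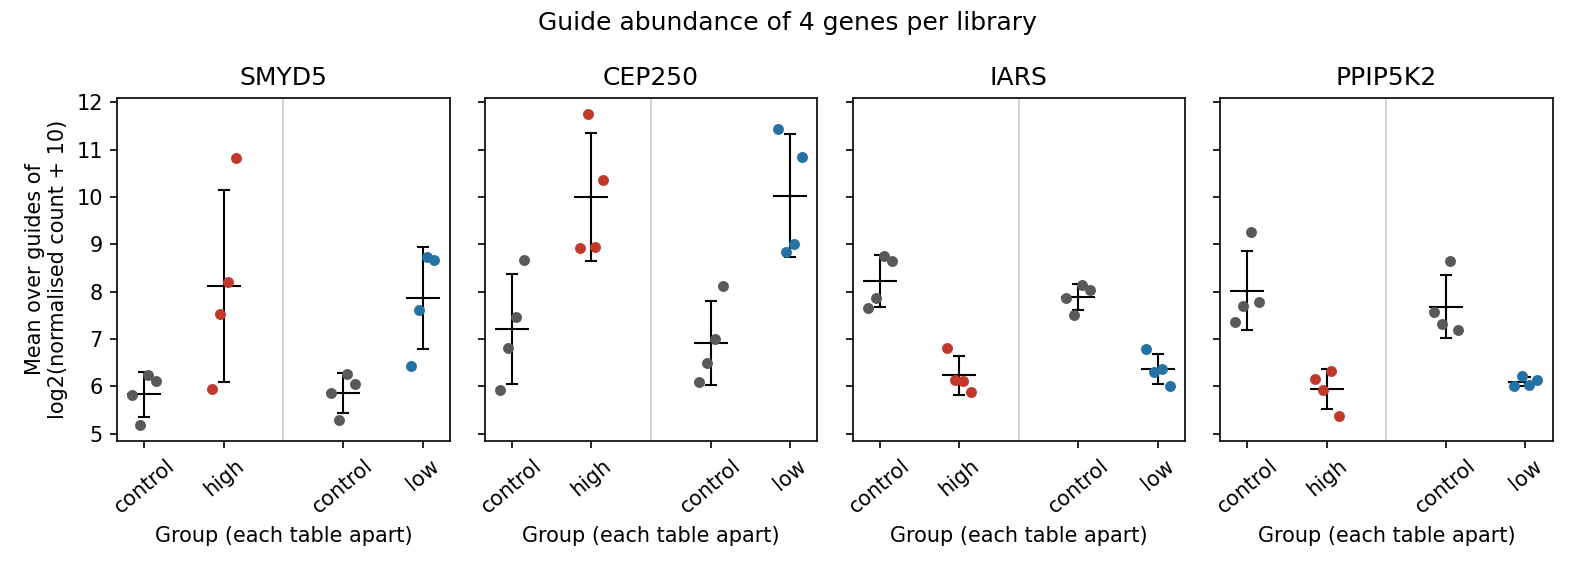
Mean over guides of log2 of the normalised count plus 10 in each library, for SMYD5, CEP250, IARS and PPIP5K2 (points are libraries, bars the mean ± SD, n = 4 per group, with the controls shown as each table scales them). SMYD5 rose from 5.86 to 7.86 in low against control; its values of 5.83 in control and 8.12 in high did not pass the test, and IARS and PPIP5K2 lie lower in both sorted groups without passing it.

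limma called 721 of 20123 genes, and 4008 had an unadjusted p under 0.05, 3891 of them higher and 117 lower. The median change of all genes was 0.48. Random groups of 5 non-targeting guides were called in 5 of 195 cases (2.56%), against 3.65% of all genes (Fisher's exact p = 0.563). Genes and groups are not independent replicates. Genes with fewer kept guides were called more often, and those with 5 or more at 2.76% (428 of 15532), near the share of the groups. The median change of the groups was 0.63, larger than that of genes. Of the groups 24.1% had an unadjusted p under 0.05, against 20.0% of genes. Of 105285 guides, limma called 0 (11985 at an unadjusted p under 0.05) and, with the replicate block, 59, all higher. Rescaled to the same total 1 gene rose and 12257 fell, with a median of −1.81 over all genes, and rescaled to the non-targeting guides 3781 rose and 0 fell, with a median of 0.82; these counts follow the shift of all genes. With the median of all genes set equal in every library, a test chosen after the data had been seen, 37 of the 721 rose and 0 genes fell, and SMYD5 had a change of 1.62 (adjusted p = 0.171). With the replicate block 926 genes rose and 1 fell. edgeR called 27 genes higher and 847 lower, 18 of them among the 721, and rank aggregation of guides called 0. Relative to the median of all genes, SMYD5 stood at 1.52 as deposited, 1.23 at the same total and 1.5 on the non-targeting guides, and all 26 genes named by rule kept their side of that median under these 3 scalings.

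None of the 13 risen genes that the rule named by size, by the authors' tables or beforehand passed with the median or the sum over guides, with rank aggregation or in replicates 3 and 4 alone. Their changes stayed positive, such as 4.11, 5.10, 3.83 and 3.10 for RNASE2 and 0.68, 3.57, 2.09 and 2.71 for FAM102B in that order. The count also rested on single libraries. It was 53 without control 3, 100 without control 1, 358 without control 2, 405 without control 4 and 223 without low 4. Replicates 1 and 2 alone gave 8 and replicates 3 and 4 alone 0, and without the 5 libraries that shared their most abundant guides 2 genes were called. In low against control SMYD5 passed without low 1 (change of 2.47) but not without any other library, where its change was between 1.45 and 2.00 and its adjusted p between 0.0747 and 0.171. RNASE2, RABGAP1, RGS21, CEP250 and hsa-mir-3944 passed without each single library; GPR157, ACTG2 and KRTAP9-2 did not pass without control 3 (changes of 3.60, 3.02 and 2.79), PNMA6A not without control 1 (2.53) or control 3 (2.53), and TMEM108 not without control 1 (2.26), control 3 (2.51) or low 4 (1.73). Without guide HGLibA_45862 the change of SMYD5 was 1.59 (adjusted p = 0.0721), and without each other guide it stayed past the threshold. In low, SMYD5 guides of library part A changed by 3.62, 1.88 and 2.58, and those kept from part B by 0.55 and 1.37. Against high the parts overlapped, with 2.88, 2.78 and 1.54 in part A and 0.46, 2.59 and 3.49 in part B. For SP1, CIRBP and RBM3, each guide of part A also lay above each guide of part B in low. Whether the library part sets these differences was not tested.

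The authors' deposited table for low against control holds 0 genes enriched and 1 depleted, IARS, at an FDR under 0.05 (FDR 0.00495). CEP250 led the enriched genes of the authors' deposited table (FDR 0.0545), followed by FAM102B, hsa-mir-3944, PDS5B, a cohesin regulator, and SYT1, the calcium sensor of synaptic vesicles (FDR from 0.126 to 0.183). After IARS the authors' deposited table lists PSMA4, OR10R2, EPM2AIP1 and ELMO3 as depleted (FDR from 0.127 to 0.212). For PDS5B (−0.40) and ELMO3 (1.55) the authors' own log2 fold change went against the listed direction. In the limma fit SYT1 rose by 2.41 and FAM102B by 1.78, while PDS5B (0.27), PSMA4 (−0.59), OR10R2 (−1.15), EPM2AIP1 (−1.37) and ELMO3 (0.85) did not pass. Without 1 library PDS5B was between −0.22 and 0.57, PSMA4 between −0.85 and −0.34 and ELMO3 between 0.42 and 1.36. SYT1 did not pass without control 1 (1.99) or control 3 (2.22) and rose by 4.04 without control 2, and FAM102B passed when control 2 was left out (2.55) but not without any other library (1.49 to 1.83). SMYD5 ranked 795 among enriched genes of the authors' deposited table (FDR 0.377). Of the 721 genes, 539 had a p under 0.05 for enrichment in the authors' deposited table, and the fold changes had a Spearman correlation of 0.776 across genes.

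High against low compares the tails of the reporter signal within the reporter line, each taken against the controls of its own table. SMYD5 had a difference of 0.66 (SE 1.02, n = 4 per group, 95% interval −1.34 to 2.65), with 3 of 5 guides and 2 of 4 pairs higher in high; it was −0.29 without high 4, 0.18 without low 1 and 1.62 without high 1. C7, a complement component, stood 1.44 higher in high (SE 0.62) and PIK3IP1, an inhibitor of phosphoinositide 3-kinase, 1.13 higher (SE 0.49), and neither passed. FXYD4, a regulator of the sodium pump, differed by −1.92 (SE 0.49), SFMBT2, a Polycomb group protein, by −1.98 (SE 0.55), and TMEM88B by −1.22 (SE 0.33), and none of them passed (adjusted p = 0.998 for each).

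SLC6A12, a betaine transporter, PASD1 and RD3L had differences of 1.36, 1.35 and 1.21, and ZNF280D, a zinc finger protein, and SPACA3, a sperm acrosome protein, of −1.62 and −1.60. Without 1 library C7 differed by 0.84 (high 4 left out), SLC6A12 by 0.77 (high 3), PASD1 by 2.56 (high 1) and SPACA3 by −1.02 (low 2). SP1 differed by 0.39 (−0.04 to 0.71 without 1 library), CIRBP by −0.43 (−0.83 to −0.25) and RBM3 by −0.60 (−1.21 to −0.29). KLF6 had a difference of −1.95 (SE 0.86) among 26 SP and KLF factors, and 14 of 15 m6A genes had lower values in high, with YTHDC1, a nuclear reader, at −1.11; 0 members of these lists passed by either adjustment. limma called 0 of 20109 genes, with 873 at an unadjusted p under 0.05, 869 of them lower in high, and a median difference of −0.29. This lean to lower values went with the scaling and with the libraries used. At the same total 132 genes had an unadjusted p under 0.05 and the median was 0.07, and on the non-targeting guides 312 and −0.06. Without the 5 libraries the values were 890 and 0.06, and 0 genes were called under each of these settings. edgeR and rank aggregation called 0 genes as well. Of 104863 guides 0 were called, with 2162 at an unadjusted p under 0.05, and 0 of 32 lists were shifted (smallest adjusted p of camera 0.487, for the m6A list). In simulated data the same test recovered 78% of rises of 4 and 4% of rises of 2, so a difference near the value of SMYD5 was not detectable with these replicates.

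Changes in high and in low against the shared controls ran together. Across 20111 genes their Pearson correlation was 0.763, and 77.7% of genes had the same sign. Unchanged groups simulated against shared controls gave a mean correlation of 0.397, from −0.01 to 0.787. The mean share of genes of the same sign was 65.2% in them, from 49.5% to 79.6%. Both observed values lie within the simulated ranges. These ranges are too wide to show whether the shared controls account for the observed values. With separate pairs of controls for high and low the correlation was 0.340 (0.266 to 0.412 over 6 ways of splitting) and the share of the same sign 62.8% (57.7% to 68.7%), for which no value without change was computed.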

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

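The tests of sorting as a source of shared guides, of scaling, of non-targeting groups and of the high minus low difference of SMYD5, and the setting without 5 libraries, were chosen after the results had been seen.

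Of 151 groups of 4 libraries tested, 15 had a library far from the other 3, where chance gives about 1 in 20. Low 1 had a Gini index of 0.2451 (others 0.369 to 0.375), 5726 guides without reads (others 12482 to 12818) and a median of 130 reads per guide (others 17 to 18). Median reads per guide also stood apart in control 1 (1778, others 63 to 217) and high 1 (68, others 21 to 28), and these are the replicates with merged read files. Low 2 had an effective number of 9692 guides, against 1434 to 2458 in the other low libraries. The difference of essential against non-targeting guides was −1.59 in control 4 (others −0.96 to −0.91) and −1.03 in low 1 (others −1.29 to −1.27).

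Single genes stood apart in 1 library each. In the table of high and control, LRRC26 had a log2 value of 10.1 in high 4 (others 6.68 to 7.23), OR10R2 of 7.86 in high 4 (others 7.0 to 7.07) and EPM2AIP1 of 7.43 in control 1 (others 8.86 to 9.06). In the table of low and control, CIRBP had 6.07 in control 2 (others 7.11 to 7.22), TMEM108 13.3 in low 4 (others 8.98 to 9.10) and PPCDC 6.79 in control 4 (others 7.64 to 7.77). ZNF280D, taken relative to control, had −0.59 in high 3 (others −0.95 to −0.91).

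The same guides were most abundant in control 2, control 4, high 1, high 3 and low 3, which differ in group and in day. Sorting by reporter signal would give libraries of different groups different guides, but control 2 and high 1 shared 16.96 times the number chance gives. This overlap is part of the pattern itself, so it is not a separate test of sorting. An uneven starting library would favour the same guides in every library, but a median of 18.96% of the 3819 guides were among the most abundant of the other 7 libraries (16.1% to 30.0%), which is above the 5% of chance and may explain a part. Reads or cells carried between these libraries remain a candidate explanation, since within the shared guides read counts rose together (median Spearman correlation 0.827 over 10 pairs, and 0.130 over the other 56 pairs). The step at which this could have happened was not tested.

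Guides of 721 genes rose in low against control and guides of 0 genes fell. Among the 35 splits of the 8 libraries into 4 and 4, 1 gave as many calls, the real one, and the highest of the others gave 1 call. This is the smallest share the test can give, and it takes the libraries as unpaired. The 8 splits that part all 4 pairs are too few for a share under 0.05 (highest other 0). As the replicate numbers pair the libraries, chance was not excluded. Loss of the targeted genes as the source of the rises would make the guides of a gene change together, but the variance of gene means was 1.0032 times that of guides assigned to genes at random and within the range of 100 such assignments. The scaling of the deposited values may set most of the number, as 37 of the 721 were called and 0 genes fell with the median of all genes set equal in every library. So may a spread that does not depend on the target, as 5 of 195 non-targeting groups were called, 0.702 times the rate of all genes. These groups hold 5 guides each, and genes with 5 or more kept guides were called at 2.76%, near the 2.56% of the groups. The median change of the groups was 0.63, against 0.48 for genes. Scaling and such a spread both stay open, and rises of single genes within this excess were not excluded.

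SMYD5 guides were more abundant in high and in low than in control as deposited, past the threshold in low, but at the same total the change in low was −0.58, and by share of reads SMYD5 lay below the paired control in high 1, high 3, low 1 and low 4. At the same total the median of all genes fell as well. Relative to that median SMYD5 stood at 1.23 in low and 2.20 in high, so its direction did not reverse relative to other genes. Low values in the shared controls may contribute: the mean of SMYD5 lay at percentile 2.73 of genes in the controls of the high table and 5.21 in those of the low table, against 73.9 in high and 63.7 in low, where single libraries lay at 2.81 to 15.2, 5.28 to 24.6, 11.9 to 95.9 and 17.5 to 83. A change common to genes of like control level cannot be told apart from one of its own, since 99.6% of the 500 nearest genes changed by less in high and 97.6% in low, between the bounds set for either reading. A gain in reporter signal on loss of SMYD5 cannot be told apart either, as the difference of high minus low was 0.658 with a 95% interval of −1.34 to 2.65. The controls also lack the reporter, so line and sorting change together in both comparisons with control.

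For the other results of fits across genes the real split gave 0, so that all 35 of 35 splits count as at least as large by construction, which says nothing about chance. The highest other split gave 51 genes in high against control (control 1 to 3 with high 1 against the rest) and 240 in high against low (high 1 to 3 with low 1 against the rest). Such numbers may point to a structure of the samples other than the groups, which was not tested. For guides the highest other split gave 0 in all 3 comparisons, and for gene lists it gave 0 in high against control, 1 in low against control and 1 in high against low. Splits that follow the 2 months gave 0 genes in each comparison.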

How the results depend on the processing

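The setting without 5 libraries and the paired tests of essential gene guides were chosen after the data had been seen. Several counts stayed on their side of the threshold, or within the spread of replicates, under every setting run for them. These were genes and guides in high against low, guides in high against control and gene lists shifted in each comparison. They also included non-targeting groups in the comparisons other than low against control. The Gini index, the share of reads in the most abundant guides and the essential gene guides did so too. For these library measures, exact tests with replicates left out could not have passed the threshold. Within replicates 1 and 2 or 3 and 4 alone, the smallest possible p of the exact permutation test was 0.333. For the paired sign tests of essential gene guides it was 0.125. Such settings therefore do not show that these measures were stable. Reads per guide are a limit: in the sorted libraries the median guide had between 17 and 130 reads. The most abundant 5% of guides held between 52.5% (high 4) and 91.8% (high 1) of the reads of these libraries. For each change given here the cause was not tested, except that leaving out libraries leaves fewer samples and that medians over guides recovered fewer simulated rises.

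Genes called in high against control went from 0 to 12451 at the same total, 1822 on the non-targeting guides, 186 without the 5 libraries and, without 1 library each, to between 0 and 45. Genes called in low against control went from 721 to 389 at a pseudocount of 50, 1159 at a filter of 100, 0 with the median over guides, 0 with the sum over guides, 12258 at the same total, 3781 on the non-targeting guides, 8 in replicates 1 and 2, 0 in replicates 3 and 4, 2 without the 5 libraries, 0 with rank aggregation, and to between 53 and 787 without 1 library each. With edgeR the count was 874, but 847 of these were lower. With the replicate block it was 927 (926 rises, 1 fall), which hold all of the 721, and guides called in low against control went from 0 to 59; the block changed no other count of genes, guides or lists past the limits used here. Non-targeting groups called in low went from 5 to 8 in another grouping. The authors' deposited tables hold 8 genes in high and 2 in low at an FDR under 0.1, against 2 and 1 at 0.05. The correlation of changes in high and low went from 0.763 to 0.340 with the controls split. The difference in guides without reads, 230 for high and 15.5 for low, was between −1223 and 1394 and between −192 and 461 without 1 replicate each.

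Among named genes, 51 values of single genes changed sign. At the same total, where the median of all genes fell as well, these were in high SP1 (−1.89), RBM3 (−1.73), HOXB4 (−0.10) and MUC15 (−0.60), and in low SMYD5 (−0.58), CIRBP (−1.92), RBM3 (−1.55), FAM102B (−0.29), PDS5B (−1.81) and ELMO3 (−1.07). On the non-targeting guides CIRBP in high was 0.54 and SP1 in low 0.0761. In high, SP1 was −0.56 with the median over guides, −0.0248 in replicates 1 and 2, −0.40 with library weights and between −0.33 and 0.42 without 1 library each. CIRBP in high was 0.10 at a pseudocount of 1, 0.34 with the sum over guides, 0.12 in replicates 1 and 2, 0.52 with library weights, 0.72 with edgeR and between −0.45 and 0.17 without 1 library each. RBM3 in high was −0.32 in replicates 1 and 2, −0.0622 with library weights and between −0.29 and 0.64 without 1 library each. In low, SP1 was 0.0812 without the 5 libraries, and CIRBP was −0.42 with the median over guides, −0.0633 in replicates 3 and 4 and −0.28 with rank aggregation. PDS5B in low was −0.61 in replicates 1 and 2, −0.77 without the 5 libraries, −0.33 with rank aggregation, −0.14 with edgeR and between −0.22 and 0.57 without 1 library each. PSMA4 in low was 0.33 with the sum over guides and ELMO3 −0.0825 in replicates 3 and 4. In high against low, SMYD5 was −0.58 with edgeR and between −0.29 and 1.62 without 1 library each, SP1 was −0.38 with the median over guides, −0.14 with library weights and between −0.0434 and 0.71 without 1 library each, CIRBP was 0.16 with library weights and RBM3 0.28 without the 5 libraries. Of the other values of named genes, 1326 kept their direction and side of the threshold, 121 no longer passed and 43 passed where they had not.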

Other observations

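In low against control, several lists not described so far had 1 or 2 members past the threshold over all genes. Among them were 2 of 31 in TFIID and the general transcription factors (5 adjusted over the list alone), and 1 each of 23 in SAGA and ATAC (3), 15 in NuA4 (2), 28 in Polycomb (1), 15 in heterochromatin and DNA methylation (2), 45 translation initiation factors (1), 32 in the core spliceosome (1), 12 in RNA polymerase II (1) and 20 growth restraining genes (1). COMPASS, the histone deacetylase corepressors, the H3K36 and H4K20 methyltransferases, mTORC1 activators, the integrated stress and unfolded protein response, and the cullin ligases had 0. With limma 0 genes of any list passed in high against control over all genes. Adjusted over the list alone, 1 member passed in each of 3 lists, among them GATAD2A of 29 deacetylase corepressors with a change of 1.75.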
